A study of Mus musculus with 15 samples.

How the data were processed

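Total RNA of mouse liver (15 to 20 mg of tissue each) was labelled with biotin by the submitters and read on Illumina arrays of 45281 probes, 1 array per sample. Nothing in the sources used here says whether each array is a separate animal, so an error here measures the spread between samples. The deposited file of array signals gives, per the file headers and values, an intensity for each probe and array on a linear scale, not normalized between arrays, and a detection p-value, the share of negative control probes brighter than the probe. The deposited value table of the series holds an intensity quantile-normalized by the authors, on a linear scale with no visible background subtraction. Partek 6.60 is named in the submitters' notes without a role, and the scanner software and background handling are not given in the sources used here.

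The signals were corrected for background with the detection p-values, quantile-normalized and turned to log2 with neqc of limma 3.58.1 (offset 16; R 4.3.3). A probe was kept if its detection p was under 0.01 on at least 3 of the 15 arrays, which held for 15361 probes. 34885 probes had 1 gene in the probe table, 18 several and 10378 none. Each gene was read from its probe with the highest mean, which left 8976 genes, 3085 of them with 2 or more detected probes. Among these, 2 genes had probes called in both directions in the chronic comparison and 10 between the baselines. Of those with a called probe, 80 of 94 in the acute and 661 of 904 in the chronic comparison had another not called, such as dimmer probes of Usp2 (0.097) and Lonrf3 (-0.011) after acute and of Thrsp (0.24), Lss (-0.26) and Cyp2d22 (0.37) after chronic T3. Of 2884 probes called in the chronic comparison with each probe tested, 352 had no single gene and were not used in the main test. A gene called not well above background in a group was detected on none of its 3 arrays, and its fold is then a bound against the lowest detected signal of those arrays.

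All 15 arrays entered 1 limma fit with a mean per group, 10 residual and 13.1 moderated degrees of freedom, and 2-sided tests were adjusted by Benjamini-Hochberg over all genes tested in each comparison. The comparisons were acute T3 against baseline A, chronic T3 and T3 withdrawal against baseline B, T3 withdrawal against chronic T3, the difference of the chronic and the acute effect, and baseline B against baseline A. A permutation test of 3 arrays against 3 cannot go below p = 0.1, so that single genes were tested with limma's moderated test alone. 32 gene lists were fixed before the data were examined. 30 with at least 3 measured members were tested with camera (preset correlation 0.01), and with an estimated correlation and fry as alternatives. The list of neutrophil markers (2 of 12 genes measured) and that of adipose tissue markers (1 of 10) were not tested. The lists share members, such as Thrsp in T3-induced and fatty acid synthesis genes, and many of their genes are expressed by hepatocytes too.

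Genes were named by a rule fixed before the data were examined: the 10 largest rises and 10 largest falls of each of the acute, chronic, withdrawal and difference comparisons among called genes with no overlap of arrays (5 and 5 for the others), 18 genes chosen for the question, up to 4 members of each list with the smallest adjusted p, and 5 and 5 genes of each combined count. Predicted and RIKEN-type symbols were not named. The alternatives were other background corrections, scalings, filters, probe summaries and variance moderations, array weights, the authors' values, fits on fewer arrays, other thresholds, and leaving out each array in turn. Gene list tests were not run without moderation, on every probe, or with a fold threshold. No slide is named for any array, so a slide block was not run.

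Replicate numbers might pair arrays between groups, which was checked by correlating the residuals of arrays with the same number. The lowest such r was -0.281 in the acute, -0.198 in the chronic, 0.00529 in the withdrawal comparison and -0.0451 between withdrawal and chronic T3, so these were not treated as paired. Between the baselines the r were 0.126, 0.250 and 0.195, which leaves pairing there open. The values printed come from the fit without a block, fixed before the data were examined, and the replicate number as a block (replicate block) was an alternative for every count.

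The pipeline was tested on data simulated with these arrays' spread. In the acute comparison it found 15 of 67 genes changed 1.5-fold, 49 of 67 changed 2-fold and 64 of 66 changed 4-fold. Of 138 calls 10 were wrong. Residual draws (below) reached 525 false reversals, so real errors may be more frequent. The Y-linked Eif2s3y was detected on all 15 arrays and Xist on 0. Counts were set beside those of other splits of the arrays, all 10 for 3 against 3 and 100 drawn with a fixed seed for more groups. With 3 groups each split was counted once whatever their order, because draws had repeated the real groups in other roles. With 4 groups each T3 group kept the role of the real group it shared most arrays with. Both rules were set after values were seen. Counts and correlations that share arrays were also simulated from the residuals in 100 draws. Shared cages, days or times of killing are not given in the sources used here. Figures were drawn with matplotlib 3.10.9.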

Results

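Gene expression was measured in liver of 8-week-old male C57BL/6 mice on 15 Illumina bead arrays, in 5 groups of 3. T3 (liothyronine) is the active thyroid hormone. Mice of the acute T3 group were killed 6 h after 1 intraperitoneal injection of 20 µg T3 per 100 g body weight. Mice of the chronic T3 group were killed 6 h after the last of 14 daily injections, and mice of the T3 withdrawal group 10 days after the last of 14. The work was done in 2 experiment subsets, each with its own untreated group: baseline A went with acute T3, and baseline B with chronic T3 and T3 withdrawal. No injections are given for either baseline group. With no group known to be injected without T3, effects of T3 and of the injections cannot be told apart. The arrays had a mean signal of 435 to 697, and 11049 to 14679 of 45281 probes were detected on each. The dimmest were chronic T3 replicates 2 and 3 (mean signals 438 and 435). Having 3 arrays a group limits the precision of every value. The first principal component (31.8% of the variance) set the 3 chronic T3 arrays apart from the 12 others. Each gene's value is a log2 difference between 2 groups ± its moderated standard error (n = 3 arrays a group), and genes that rose or fell passed an adjusted p of 0.05 over the 8976 genes tested.

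The acute comparison, acute T3 against baseline A, asks which liver genes respond within hours of 1 dose of T3. Thrsp, a classical T3 target, rose by 3.30 ± 0.32 (9.84-fold; adjusted p = 0.000442). Thrsp was also 3.09 higher in untreated baseline B than in A. The same direction was called there for 52 of the 190 acute genes, Dbp, Usp2, Chka, Arntl and Cdkn1a among them. The acute values of these genes may rest in part on baseline A. Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase, rose by 1.60 ± 0.28, and Dio1, the deiodinase that both activates and clears thyroid hormone, by 1.44 ± 0.27. Bcl3, a cofactor of NF-kappa B, rose by 1.46 ± 0.28, and Cyp7a1, the rate-limiting enzyme of bile acid synthesis, by 1.56 ± 0.33. The largest rise was that of Dbp, a clock-controlled transcription factor (3.61 ± 0.60; 12.2-fold). Other large rises were those of Crybb3 (3.16 ± 0.64), Ttbk1 (2.85 ± 0.31), Cpsf4l (2.36 ± 0.30), Sbk1 (2.25 ± 0.35), Cela2a (2.15 ± 0.24) and Wipf3 (2.04 ± 0.20), of Usp2, a rhythmic ubiquitin protease (2.03 ± 0.43), and of Acot11, an acyl-CoA thioesterase that was not well above background in baseline A (at least 6.42-fold higher). The largest falls were those of Chka, choline kinase alpha (-2.32 ± 0.26), of Arntl, the core clock factor BMAL1 (-2.25 ± 0.30), and of Cdkn1a, the cell cycle inhibitor p21 (-2.07 ± 0.22). Gclc of glutathione synthesis fell by 1.42 ± 0.31 on the log2 scale, the stress-responsive Nupr1 by 1.54 ± 0.32, and Ndrg1 (-1.66 ± 0.29), Lonrf3 (-1.58 ± 0.35) and Wsb1 (-1.39 ± 0.32) fell as well. The immediate early gene Fos (at least 2.89-fold lower) and the glycogen-targeting subunit Ppp1r3g (at least 2.95-fold lower) were not well above background after acute T3. Among the other genes fixed beforehand, Me1 (0.72 ± 0.28), Fasn (1.69 ± 0.41; adjusted p = 0.0509), Hr (0.41 ± 0.38), Klf9 (-0.15 ± 0.15), Fgf21 (-1.54 ± 0.68), G6pc (0.52 ± 0.42), Pck1 (0.012 ± 0.24) and Cyp8b1 (0.62 ± 0.22) did not pass, and Cpt1a, Thrb and Thra were not tested because their probes were not detected on enough arrays. Bcl3 and Dio1 lost the call without baseline A replicate 1, or acute T3 replicates 1 or 3 (adjusted p 0.0627 to 0.0891). Crybb3 lost the call without any 1 array compared but baseline A replicate 3 (adjusted p 0.0625 to 0.107). Cyp7a1 lost the call without any 1 array compared but acute T3 replicate 1 (adjusted p 0.0705 to 0.114). Gclc, Lonrf3 and Nupr1 lost the call without any 1 array compared (adjusted p 0.0515 to 0.151). Ndrg1 lost the call without baseline A replicate 1 or acute T3 replicate 3 (adjusted p 0.0619 to 0.0625). Ppp1r3g lost the call without any 1 array compared but baseline A replicate 2 (adjusted p 0.0675 to 0.149). Usp2 lost the call without baseline A replicates 1 or 2, or acute T3 replicates 2 or 3 (adjusted p 0.0874 to 0.137). Wsb1 lost the call without any 1 array compared but acute T3 replicate 2 (adjusted p 0.0652 to 0.182). Fos lost the call without baseline A replicate 2, or acute T3 replicates 1 or 3 (adjusted p 0.0561 to 0.0906). Acot11 lost the call without acute T3 replicate 1 (adjusted p = 0.0620), and Gpd2 without replicates 1 or 3 (0.0561 to 0.0625). Dbp was 3.02 without baseline A replicate 1. Without replicate 3, Dbp was 4.63, Crybb3 3.76 and Usp2 2.67. Ppp1r3g lost the call under no background correction and normexp (adjusted p 0.0638 to 0.0826). Gclc, Nupr1 and Wsb1 lost the call under median scaling (adjusted p 0.0560 to 0.175).

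By lists, 5 of 17 measured members rose and 12 did not pass among T3-induced liver genes (8 rose adjusted over the list alone; camera adjusted p = 6.27e-05; adjusted p = 0.0852 with an estimated correlation). In cholesterol synthesis and uptake, 5 of 17 measured members rose and 12 did not pass (8 rose adjusted over the list alone), with Mvd (2.01 ± 0.29), Msmo1 (1.98 ± 0.23), Sqle (1.91 ± 0.35) and Hsd17b7 (1.33 ± 0.20) among them (camera adjusted p = 1.61e-06; adjusted p = 0.338 with an estimated correlation). The same list was also higher in baseline B than in baseline A, both untreated, by a mean of 0.58 (camera adjusted p = 0.000307; adjusted p = 0.536 with an estimated correlation). In fatty acid synthesis 1 of 21 measured members rose and 20 did not pass, the riser being Thrsp (5 rose adjusted over the list alone; camera adjusted p = 0.0145; adjusted p = 0.449 with an estimated correlation), and the list's median was 0.073 beside a mean of 0.48. In bile acid synthesis and transport 1 of 19 measured members rose and 18 did not pass, the riser being Cyp7a1, while Abcg8, a sterol exporter, had a value of 0.81 ± 0.22 (3 rose adjusted over the list alone; camera adjusted p = 0.0209; adjusted p = 0.338 with an estimated correlation). In mitochondrial biogenesis 1 of 16 measured members rose and 15 did not pass, the riser being Gpd2, and the coactivator Ppargc1b had a value of 1.33 ± 0.34 (3 rose adjusted over the list alone; camera adjusted p = 0.0209; adjusted p = 0.140 with an estimated correlation). Clock genes went both ways: 5 of 14 measured members rose, 2 fell and 7 did not pass (8 rose and 3 fell adjusted over the list alone), among them Tef (1.20 ± 0.25) and Clock (-0.55 ± 0.11) beside Dbp and Arntl (camera adjusted p = 0.0115; adjusted p = 0.420 with an estimated correlation). The clock list differed by a mean of 1.18 between the 2 baselines as well (adjusted p = 0.423 with an estimated correlation). Clock and Tef lost the acute call without baseline A replicates 1 or 2, or acute T3 replicates 1, 2 or 3 (adjusted p 0.0589 to 0.121). Sqle lost the acute call without baseline A replicate 1, or acute T3 replicates 1 or 3 (adjusted p 0.0620 to 0.0739). The bile acids list lost the acute call without baseline A replicate 2 or acute T3 replicate 3 (adjusted p 0.0822 to 0.115). The clock list and the fatty acid synthesis list lost the acute call without baseline A replicate 2 (adjusted p 0.0542 to 0.0692). The mitochondrial biogenesis list lost the acute call without acute T3 replicate 3 (adjusted p = 0.0822). Clock lost the acute call under median scaling (adjusted p = 0.618).

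Lists lower after acute T3 held few called genes. In the immediate early and heat shock list 1 of 13 measured members fell and 12 did not pass, the gene being Fos, and the growth factor-induced Egr1 had a value of -1.85 ± 0.58 (3 fell adjusted over the list alone; camera adjusted p = 0.000309; adjusted p = 0.0852 with an estimated correlation). In fatty acid oxidation and PPAR alpha targets 0 of 33 measured members passed (8 had an unadjusted p under 0.05), with Ehhadh of peroxisomal oxidation at -0.72 ± 0.17 and the thioesterase Acot1 at -1.17 ± 0.33 (1 fell adjusted over the list alone; camera adjusted p = 0.0209; adjusted p = 0.452 with an estimated correlation). Among endothelial markers 0 of 15 measured members passed (3 had an unadjusted p under 0.05), with Gpr182 at -0.43 ± 0.15 and Ptprb at -0.41 ± 0.15 (0 passed adjusted over the list alone; camera adjusted p = 0.0176; adjusted p = 0.486 with an estimated correlation). The cell cycle list was called lower although its called member rose: 1 of 26 measured members rose and 25 did not pass. That member was Rrm2, a subunit of the enzyme that makes deoxyribonucleotides, which was not well above background in baseline A (at least 1.87-fold higher), while the replication helicase gene Mcm6 had a value of -0.92 ± 0.25 (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0417; adjusted p = 0.661 with an estimated correlation). Rrm2 lost the call without baseline A replicates 1 or 2, or acute T3 replicates 1 or 3 (adjusted p 0.0581 to 0.0857). The endothelial markers list lost the call without baseline A replicates 1 or 3, or acute T3 replicate 3 (adjusted p 0.0575 to 0.101). The fatty acid oxidation list lost the call without baseline A replicates 1 or 2, or acute T3 replicate 2 (adjusted p 0.0527 to 0.165). The cell cycle list lost the call without baseline A replicates 2 or 3, or acute T3 replicates 1 or 3 (adjusted p 0.0616 to 0.200). The endothelial markers list had a mean of -0.31 without baseline A replicate 2. The cell cycle list lost the call under no background correction and normexp (adjusted p 0.0655 to 0.0754). The endothelial markers list lost the call under median scaling (adjusted p = 0.0634).

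In the acute comparison 190 of 8976 genes were called (limma, adjusted p under 0.05), 132 up and 58 down. All 190 had their 3 arrays of 1 group above the 3 of the other, as did 21.9% of all genes, where chance gives 10%. 10 of 30 lists were called with camera's preset correlation, and none with an estimated correlation. The count rests on every array but baseline A replicate 3. It was 57 without baseline A replicate 1, 96 without replicate 2, and 52, 82 and 48 without acute T3 replicates 1, 2 and 3, and 6 lists were left without baseline A replicate 2 or acute T3 replicate 3. The share that rose was 69.5%, and 91.9% under median scaling, which set the median of all genes at 0.14.

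The chronic comparison, chronic T3 against baseline B, asks what 14 daily doses do to the liver. Cyp4a12a and Cyp4a12b, male-biased P450 enzymes that hydroxylate fatty acids, fell by 4.93 ± 0.26 and 5.98 ± 0.31 on the log2 scale (30.4-fold and 63.1-fold lower), though probes of such near-identical copies can read each other's transcripts. Serpina7, the gene of thyroxine-binding globulin, fell (-3.77 ± 0.60), as did Etnppl (-4.99 ± 0.79), Hsd17b6 (-4.63 ± 0.39), Ddah1 (-4.23 ± 0.70), Cyp2c23 (-3.73 ± 0.15), Abca8a (-3.53 ± 0.30) and Ppp1r3g (-3.94 ± 0.44), in which Hsd17b6 acts on androgens and Ddah1 clears dimethylarginine. Olig1 was not well above background after chronic T3 (at least 6.05-fold lower). The steroid 17-alpha-hydroxylase Cyp17a1 rose by 5.25 ± 0.47 (38.1-fold; adjusted p = 9.17e-06), the progesterone-reducing Akr1c18 by 5.01 ± 0.56, the trefoil peptide gene Tff3 by 4.69 ± 0.89, and Pnpla3, a lipid droplet protein induced by feeding, by 4.35 ± 0.64. Genes not well above background in baseline B that rose were the neurotrophin receptor Ntrk2 (at least 16.6-fold higher), Rnase2a (at least 15.2-fold), the chemokine Cxcl14 (at least 12.1-fold), the sulfotransferase Sult2a2 (at least 8.99-fold), Wfdc16 (at least 6.45-fold) and Cep126 (at least 5.25-fold). Of the genes fixed beforehand, the hormone Fgf21 rose by 3.06 ± 0.68, Dio1 by 1.54 ± 0.27, Gpd2 by 1.57 ± 0.28, Cyp7a1 by 1.87 ± 0.33, Thrsp by 1.03 ± 0.32 (0.24 at a dimmer probe, not called) and Bcl3 by 1.03 ± 0.28, and the corepressor gene Hr was at least 3.11-fold higher. Me1 (0.64 ± 0.28), Fasn (0.44 ± 0.41), Klf9 (-0.10 ± 0.15), G6pc (-0.70 ± 0.42), Pck1 (-0.46 ± 0.24) and Cyp8b1 (-0.37 ± 0.22) did not pass. Bcl3 lost the call without chronic T3 replicate 2 or baseline B replicate 3 (adjusted p 0.0644 to 0.0769). Thrsp lost the call without chronic T3 replicates 2 or 3, or baseline B replicates 1 or 3 (adjusted p 0.0888 to 0.144). Without chronic T3 replicate 1, Ddah1 was -5.25, Etnppl -6.26, Hsd17b6 -5.23 and Serpina7 -4.68. Without replicate 3, Ddah1 was -3.52 and Etnppl -4.28. Rnase2a was at a fitted 7.50 without chronic T3 replicate 1, 4.43 without replicate 2 and 4.36 without replicate 3, against 5.43 with all arrays. Sult2a2 was at a fitted 3.63 without chronic T3 replicate 1 and 5.93 without replicate 3, against 4.99 with all arrays. Tff3 was 3.73 without baseline B replicate 1. Thrsp lost the call under median scaling (adjusted p = 0.119).

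Of the lists of cell type markers, that of macrophages and Kupffer cells was called after chronic T3. In it, 14 of 15 measured members rose and 1 did not pass (15 rose adjusted over the list alone; mean 1.67; camera adjusted p = 1.59e-11; adjusted p = 0.246 with an estimated correlation), with the folate receptor Folr2 (2.26 ± 0.20), the complement component C1qb (1.92 ± 0.23) and the lysozyme Lyz2 (1.62 ± 0.20). In the interferon response, 12 of 24 measured members rose and 12 did not pass (14 rose adjusted over the list alone; mean 1.03; camera adjusted p = 1.15e-05; adjusted p = 0.386 with an estimated correlation), with Gbp3 (2.61 ± 0.33), Ifi27l2a (2.05 ± 0.30) and Oas1g (2.07 ± 0.38). In the cell cycle and DNA replication, 15 of 26 measured members rose and 11 did not pass (17 rose and 1 fell adjusted over the list alone; camera adjusted p = 4.77e-05; adjusted p = 0.386 with an estimated correlation), with the cyclin Ccnd1 (2.42 ± 0.41), Mcm5 of the replication helicase (2.39 ± 0.32) and Rrm2 (1.66 ± 0.30). Endothelial markers rose in 4 of 15 members (mean 0.30; camera adjusted p = 0.0930), with Cdh5 of endothelial junctions at 0.83 ± 0.14, and in stellate cell and fibroblast markers 0 of 12 measured members passed (3 had an unadjusted p under 0.05) (mean 0.34; camera adjusted p = 0.286). The interferon response list had a mean of 0.63 without chronic T3 replicate 1.

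Some of the genes whose liver level differs between the sexes moved away from the male level, on the same arrays on which macrophage markers rose by a mean of 1.67. Of the male-biased list, 11 of 20 measured members fell and 9 did not pass (12 fell adjusted over the list alone; camera adjusted p = 5.65e-08; adjusted p = 0.246 with an estimated correlation), among them the complement component C6 (-1.91 ± 0.17) and Mcm10 (-2.23 ± 0.19) beside the Cyp4a12 genes. Of the female-biased list, 5 of 9 measured members rose, 1 fell and 3 did not pass (6 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00172; adjusted p = 0.246 with an estimated correlation), the risers including Ntrk2, Cyp17a1 and Sult2a2, and the thioesterase Acot3 was at least 3.78-fold lower. In cytochrome P450 and drug-metabolism regulators, 1 of 22 measured members rose, 12 fell and 9 did not pass (1 rose and 12 fell adjusted over the list alone), with Cyp2c29 (-3.10 ± 0.21), Cyp2d9 (-2.37 ± 0.49) and Cyp2d22 (-1.06 ± 0.13), and this list alone kept its call with an estimated correlation (camera adjusted p = 8.77e-05; adjusted p = 0.0227 with an estimated correlation). In phase II conjugation 6 of 37 measured members rose, 15 fell and 16 did not pass (7 rose and 17 fell adjusted over the list alone; camera adjusted p = 0.0135; adjusted p = 0.246 with an estimated correlation), with Ugt3a1 (-2.28 ± 0.30) down and the sulfotransferase Sult5a1 (2.71 ± 0.25) and the glutathione transferase Gstt1 (1.29 ± 0.17) up. The phase II conjugation list lost the call without chronic T3 replicate 2 (adjusted p = 0.0613). Cyp2d9 was -1.58 without chronic T3 replicate 1.

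Of metabolic lists, the first 4 below were called, none with an estimated correlation. In cholesterol synthesis and uptake 9 of 17 measured members rose and 8 did not pass (9 rose adjusted over the list alone; camera adjusted p = 0.00119; adjusted p = 0.483 with an estimated correlation), with Mvd (2.08 ± 0.29), Hsd17b7 (1.29 ± 0.20), Lss (1.26 ± 0.21) and Dhcr7 (1.05 ± 0.16). Among T3-induced liver genes 7 of 17 measured members rose and 10 did not pass (7 rose adjusted over the list alone; camera adjusted p = 0.0222; adjusted p = 0.269 with an estimated correlation). In fatty acid oxidation and PPAR alpha targets 2 of 33 measured members rose, 9 fell and 22 did not pass (2 rose and 11 fell adjusted over the list alone; camera adjusted p = 0.00236; adjusted p = 0.386 with an estimated correlation), with the receptor Ppara itself (-1.80 ± 0.26) and Acot1 (-2.27 ± 0.33) and Acaa1b (-0.67 ± 0.12) down and Fgf21 up. In glucose metabolism 1 of 25 measured members rose, 7 fell and 17 did not pass (1 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.0111; adjusted p = 0.246 with an estimated correlation), with the glucose transporter Slc2a2 (-1.24 ± 0.18), the pyruvate kinase Pklr (-1.87 ± 0.36) and Ugp2 of glycogen synthesis (-1.19 ± 0.13) down. The list was also 0.44 higher in untreated baseline B than in A (Slc2a2 by 1.72), so its fall may rest in part on baseline B. Bile acid genes moved both ways, as 2 of 19 measured members rose, 2 fell and 15 did not pass (camera adjusted p = 0.604), with Cyp7a1 up and the basolateral exporter Abcc3 (-2.64 ± 0.25) down. Fatty acid synthesis genes did so too: 3 of 21 measured members rose, 2 fell and 16 did not pass (camera adjusted p = 0.625), with the lipogenic factor Srebf1 (-1.23 ± 0.19) and the acyltransferase Gpam (-0.97 ± 0.25) down and Pnpla3 up. Gpam lost the call without chronic T3 replicates 1 or 2, or baseline B replicate 2 (adjusted p 0.0505 to 0.0649), and under median scaling (0.107).

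**Figure D1:**
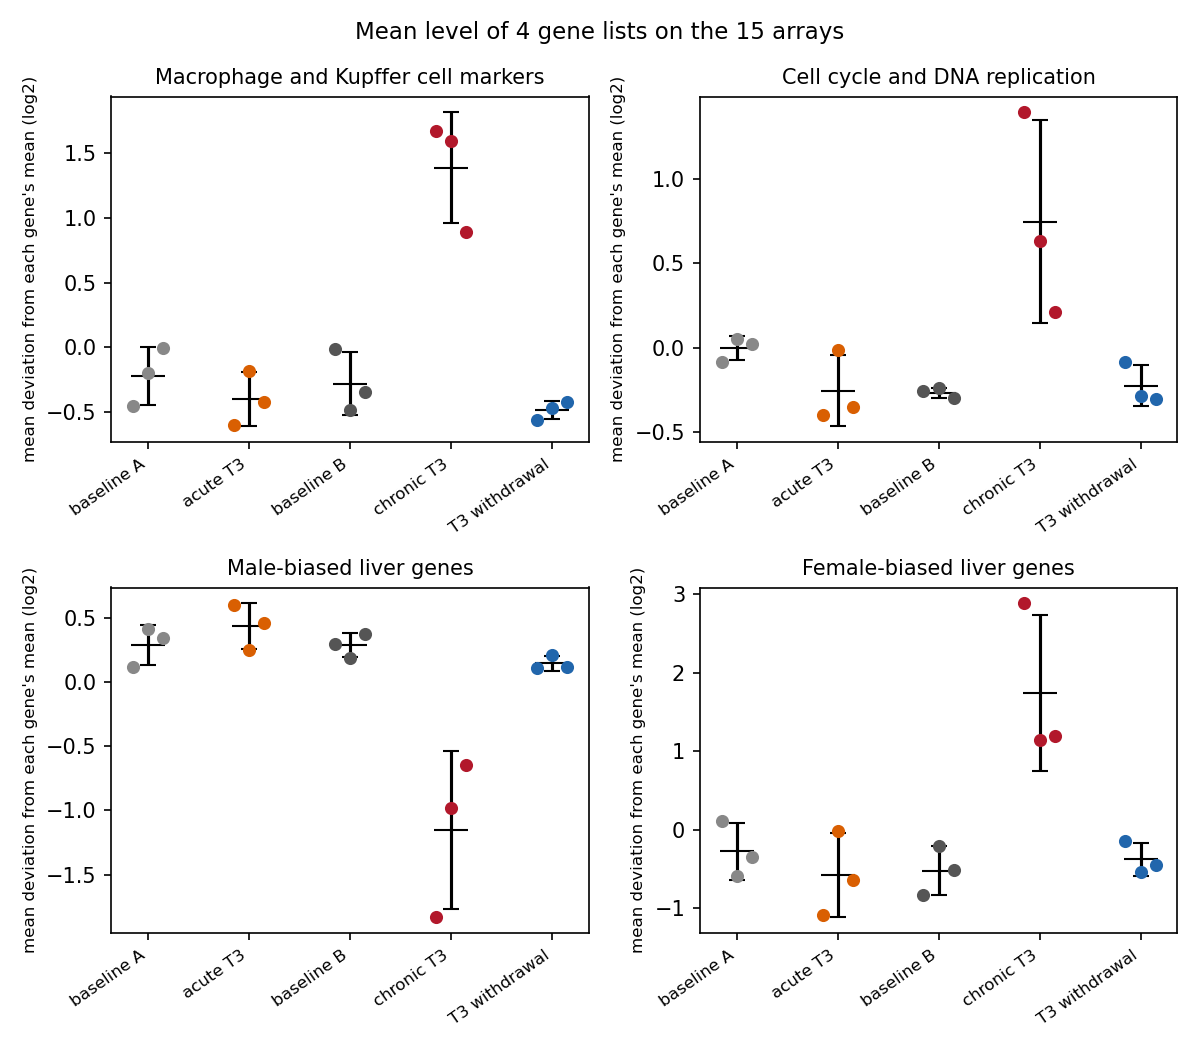
Mean over a list's genes of the log2 deviation from each gene's mean over all arrays (vertical axes), for each array (points) of the 5 groups (horizontal axes), with group means (bars) and SD (whiskers, n = 3). Macrophage markers averaged 1.39 on chronic T3 arrays and -0.28 in baseline B, and male-biased genes -1.15 and 0.29.

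In the chronic comparison 2052 of 8976 genes were called (limma), 1111 up and 941 down. 1968 of them had no overlap between the 2 groups' arrays, as did 35.3% of all genes, where chance gives 10%. The count was 888 under median scaling and 898 with only the 6 arrays compared in the fit, and 1437 without the 2 dimmest chronic T3 arrays, an alternative chosen after seeing the data.

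T3 withdrawal against baseline B asks whether the liver returns to its starting state 10 days after the last dose. The neurotrophin receptor gene Ntrk2 was still higher after withdrawal (at least 3.70-fold; adjusted p = 0.00156), and was the only gene called in this comparison. It was not well above background in baseline B. Of the genes fixed beforehand, T3 targets had values of 0.18 ± 0.32 for Thrsp, -0.81 ± 0.27 for Dio1, 0.35 ± 0.28 for Gpd2, 0.22 ± 0.38 for Hr, 0.79 ± 0.28 for Bcl3, 0.11 ± 0.28 for Me1 and -0.036 ± 0.15 for Klf9. Fasn (0.95 ± 0.41), Fgf21 (0.57 ± 0.68), G6pc (-0.86 ± 0.42), Pck1 (-0.008 ± 0.24), Cyp7a1 (0.46 ± 0.33) and Cyp8b1 (0.31 ± 0.22) did not pass either.

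9 lists were called by camera in this comparison, each with small differences and each lost with an estimated correlation. Higher were fatty acid synthesis (mean 0.32; camera adjusted p = 0.00303; adjusted p = 0.714 with an estimated correlation), with Acly, which makes cytosolic acetyl-CoA, at 0.62 ± 0.17, cholesterol synthesis and uptake (mean 0.26; camera adjusted p = 0.0115; adjusted p = 0.796 with an estimated correlation), with Lss at 0.66 ± 0.21, and the acute phase response (mean 0.26; camera adjusted p = 0.0291; adjusted p = 0.804 with an estimated correlation), with ceruloplasmin, Cp, at 0.37 ± 0.14. Lower were cytochrome P450 (mean -0.28; camera adjusted p = 0.00454; adjusted p = 0.109 with an estimated correlation), with Cyp2c29 at -0.42 ± 0.21, and phase II conjugation (mean -0.18; camera adjusted p = 0.00303; adjusted p = 0.317 with an estimated correlation), with Gstm2 at -0.85 ± 0.22. Fatty acid oxidation (mean -0.11; camera adjusted p = 0.0257; adjusted p = 0.796 with an estimated correlation) was lower, with Acot3 at -1.68 ± 0.51, and so was glucose metabolism (mean -0.17; camera adjusted p = 0.0291; adjusted p = 0.632 with an estimated correlation), with Ppp1r3g at -1.52 ± 0.44. Oxidative phosphorylation subunits (mean -0.051; camera adjusted p = 0.00811; adjusted p = 0.796 with an estimated correlation) were lower, with the complex I subunit Ndufa2 at -0.19 ± 0.091, and so were macrophage markers (mean -0.21; camera adjusted p = 0.00303; adjusted p = 0.796 with an estimated correlation), with Folr2 at -0.45 ± 0.20. No member of these 9 lists passed in limma. At an unadjusted p under 0.05 there were 4 of 21, 4 of 17, 3 of 24, 1 of 22, 4 of 37, 3 of 33, 2 of 25, 1 of 67 and 1 of 15, in the order named, and 0 passed adjusted over the list alone. The fatty acid oxidation list lost the call without T3 withdrawal replicates 1 or 2, or baseline B replicate 1 (adjusted p 0.0574 to 0.460). The glucose metabolism list lost the call without T3 withdrawal replicate 1 or baseline B replicate 2 (adjusted p 0.196 to 0.247). The cholesterol synthesis list lost the call without T3 withdrawal replicate 2 or baseline B replicate 1 (adjusted p 0.135 to 0.248). The acute phase response list lost the call without baseline B replicates 1 or 2 (adjusted p 0.0517 to 0.169). The macrophage markers list lost the call without baseline B replicate 1 (adjusted p = 0.253). The oxidative phosphorylation subunits list lost the call without baseline B replicate 2 (adjusted p = 0.214). The fatty acid synthesis list lost the call without baseline B replicate 3 (adjusted p = 0.0519). The acute phase response list had a mean of -0.0089 without T3 withdrawal replicate 2 and 0.41 without replicate 3. The fatty acid oxidation list had a mean of -0.23 without T3 withdrawal replicate 3, 0.017 without replicate 2 and -0.065 without baseline B replicate 1. The macrophage markers list had a mean of -0.31 without baseline B replicate 2 and -0.071 without replicate 1. The cholesterol synthesis list had a mean of 0.17 without T3 withdrawal replicate 2. The oxidative phosphorylation subunits list had a mean of -0.027 without baseline B replicate 2. The acute phase response list and the oxidative phosphorylation subunits list lost the call under median scaling (adjusted p 0.381 to 0.931). The fatty acid oxidation list and the glucose metabolism list lost the call under cyclic loess (adjusted p 0.0637 to 0.0793).

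The count for T3 withdrawal against baseline B was 1 of 8976 genes (limma), with 662 at an unadjusted p under 0.05, and 14.5% of all genes had groups that did not overlap, where chance gives 10%. It was 0 with only the 6 arrays compared, or only those of the experiment subset, in the fit, and 4 without baseline B replicate 2. The lists called were 5 without baseline B replicate 1 and 5 with no filter on dim probes. Median scaling set the median of all genes at 0.40 here, so that the list values are best read against that of all genes.

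T3 withdrawal against chronic T3 asks which of the chronic changes went back. The Cyp4a12 genes rose again (Cyp4a12b (5.13 ± 0.31) and Cyp4a12a (4.27 ± 0.26)), as did Hsd17b6 (3.98 ± 0.39), Etnppl (4.59 ± 0.79) and the chemokine Cxcl1 (4.02 ± 0.78). Cyp17a1 fell by 4.19 ± 0.47 and Akr1c18 by 4.93 ± 0.56 on the log2 scale, and Rnase2a (at least 19.01-fold lower), Sult2a2 (at least 11.3-fold) and Wfdc16 (at least 8.09-fold) were not well above background after withdrawal. Of the T3 targets, Dio1 (-2.35 ± 0.27), Gpd2 (-1.21 ± 0.28), Cyp7a1 (-1.41 ± 0.33) and Fgf21 (-2.49 ± 0.68) fell and Hr was at least 3.89-fold lower, while Thrsp (-0.84 ± 0.32), Bcl3 (-0.24 ± 0.28), Me1 (-0.53 ± 0.28), Fasn (0.51 ± 0.41), Klf9 (0.064 ± 0.15), G6pc (-0.16 ± 0.42), Pck1 (0.45 ± 0.24) and Cyp8b1 (0.68 ± 0.22) did not pass. Among macrophage markers all 15 measured members fell (camera adjusted p = 1.56e-16; adjusted p = 0.119 with an estimated correlation). 14 of 26 cell cycle genes and 12 of 24 interferon response genes fell (camera adjusted p = 1.13e-06 and camera adjusted p = 3.23e-07; with an estimated correlation, adjusted p = 0.368 for each). 11 of 20 male-biased genes rose (camera adjusted p = 3.23e-07; adjusted p = 0.274 with an estimated correlation), and 5 of 9 female-biased genes fell (camera adjusted p = 0.000267; adjusted p = 0.234 with an estimated correlation). Fgf21 lost the call without chronic T3 replicates 1 or 3, or T3 withdrawal replicate 2 (adjusted p 0.0586 to 0.0933). Without chronic T3 replicate 1, Etnppl was 5.86 and Hsd17b6 4.58, and without replicate 3 Etnppl was 3.88. Rnase2a was at a fitted -7.20 without chronic T3 replicate 1, -4.12 without replicate 2 and -4.06 without replicate 3, against -5.13 with all arrays. Sult2a2 was at a fitted -3.58 without chronic T3 replicate 1 and -5.88 without replicate 3, against -4.93 with all arrays. Cxcl1 was 3.33 without chronic T3 replicate 3 and 3.13 without T3 withdrawal replicate 2. Fgf21 was -3.14 without T3 withdrawal replicate 1 and -1.70 without replicate 2. Cyp7a1 and Gpd2 lost the call under median scaling (adjusted p 0.0569 to 0.0670).

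1538 genes were called between T3 withdrawal and chronic T3 (limma), 792 up and 746 down. Of the 2052 genes called after chronic T3, 1244 were called in the opposite direction on withdrawal, 627 of them chronic risers. Because both tests share the chronic T3 arrays, the count was simulated on data with no difference between withdrawal and chronic T3, where the mean was 9.38 and the highest of 100 draws 525. The 1111 chronic risers had a median of 0.827 after chronic T3 and 0.167 after withdrawal, and the 941 that fell had medians of -0.780 and -0.100. As both effects share baseline B, data with no lasting effect gave mean medians of 0.055 and -0.047 after withdrawal, and 7 and 10 of 100 draws went as far. Called in the chronic direction after withdrawal too was 1 gene, Ntrk2, with 353 at an unadjusted p under 0.05, where such data gave a mean of 3.03 and a highest of 270. Adjusted over the chronic genes alone there were 5, which are Ntrk2 and, named after their values were seen, the chaperone Dnaja1, the ribosomal protein gene Rps15a, Ddx31 and Olfr1471, and with both baselines as the control there were 4. With only the arrays compared in each fit, 802 genes were called on withdrawal and 562 reversed, and under median scaling 596 reversed, 38.1% of them risers in place of 50.4%. The share that rose on withdrawal was 51.5%, and 86.4% under median scaling, which set the median of all genes at 0.36.

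The difference of effects, chronic minus acute, each against its own baseline, asks where repeated injections act differently from 1. Values here are differences of log2 differences ± standard error, and a gap between the untreated baselines enters each of them. Cdkn1a, the cell cycle inhibitor, had the firmest difference (5.46 ± 0.31; adjusted p = 1.56e-06): it fell after acute T3, and after chronic T3 was at least 5.05-fold higher than in baseline B, where it was not well above background. The effect was more positive after chronic T3 for Tff3 (6.93 ± 1.25), Fgf21 (4.60 ± 0.96), the acyltransferase Acnat2 (4.53 ± 0.40), Cyp17a1 (4.08 ± 0.66) and the trypsin inhibitor Spink1 (3.92 ± 1.09). The differences of Akr1c18 (5.82 ± 0.79), Hr (2.36 ± 0.54), Sult2a2 (4.93 ± 1.10), Cxcl14 (4.72 ± 0.48) and Ntrk2 (4.46 ± 0.39) rest in part on signals not well above background. It was more negative for Cyp4a12b (-5.61 ± 0.44), Cyp4a12a (-4.77 ± 0.37), Ddah1 (-4.08 ± 0.99), Nox4 (-3.67 ± 0.41), Cyp2c23 (-3.27 ± 0.21), Cyp2u1 (-3.23 ± 0.47), Ildr2 (-3.18 ± 0.42) and Serpina7 (-3.09 ± 0.85), for the clock output gene Dbp (-4.003 ± 0.85), for Rgs16, a regulator of G protein signalling with a daily rhythm in liver (-3.63 ± 0.86), and for Thrsp (-2.27 ± 0.46). Cyp2u1 was not well above background after chronic T3. Dio1 (0.10 ± 0.38), Gpd2 (-0.034 ± 0.39), Cyp7a1 (0.31 ± 0.46), Bcl3 (-0.43 ± 0.39), Me1 (-0.084 ± 0.39), Klf9 (0.054 ± 0.21), Fasn (-1.25 ± 0.57), G6pc (-1.22 ± 0.59), Pck1 (-0.47 ± 0.33) and Cyp8b1 (-0.99 ± 0.32) did not pass. Ddah1 lost the difference-of-effects call without baseline A replicate 1, acute T3 replicates 1 or 3, chronic T3 replicate 2, or baseline B replicates 1 or 3 (adjusted p 0.0580 to 0.0678). Rgs16 lost the difference-of-effects call without baseline A replicate 1, acute T3 replicate 3, chronic T3 replicate 1 or baseline B replicate 3 (adjusted p 0.0508 to 0.0665). Spink1 lost the call without any 1 array compared, except chronic T3 replicate 3 (adjusted p 0.0504 to 0.110). Serpina7 lost the call without any 1 array compared, except baseline A replicate 1 or chronic T3 replicate 1 (adjusted p 0.0620 to 0.0983). Hr lost the call without acute T3 replicate 1 or baseline B replicate 1 (adjusted p 0.0508 to 0.0542). Dbp was -3.41 without baseline A replicate 1 and -5.03 without replicate 3. Akr1c18 was 4.99 without baseline A replicate 3. Tff3 was 7.93 without acute T3 replicate 2, 6.29 without replicate 3 and 5.97 without baseline B replicate 1. Fgf21 was 5.30 without acute T3 replicate 3. Without chronic T3 replicate 1, Ddah1 was -5.09, Serpina7 -4.000, Sult2a2 3.57 and Spink1 3.14. Without replicate 3, Ddah1 was -3.37, Sult2a2 5.88 and Spink1 4.65. Hr and Serpina7 lost the call under median scaling (adjusted p 0.0827 to 0.0972). Spink1 lost the call under median scaling and cyclic loess (adjusted p 0.0518 to 0.0782).

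13 lists differed between the effects by camera's preset correlation, and none with an estimated correlation. Effects were more positive after chronic T3 for macrophage markers (11 of 15 measured members rose and 4 did not pass; camera adjusted p = 7.50e-14; adjusted p = 0.192 with an estimated correlation), among them Folr2 (2.10 ± 0.28) and Lyz2 (2.09 ± 0.28), and for the cell cycle (9 of 26 measured members rose and 17 did not pass; camera adjusted p = 8.29e-07; adjusted p = 0.319 with an estimated correlation), with Mcm5 at 3.18 ± 0.45. The interferon response (4 of 24 measured members rose and 20 did not pass; camera adjusted p = 0.000575; adjusted p = 0.459 with an estimated correlation), with Ifi27l2a at 2.35 ± 0.43, and female-biased genes (3 of 9 measured members rose and 6 did not pass; camera adjusted p = 0.000186; adjusted p = 0.266 with an estimated correlation) went the same way. So did endothelial markers (3 of 15 measured members rose and 12 did not pass; camera adjusted p = 0.00234; adjusted p = 0.401 with an estimated correlation), with Cdh5 at 0.99 ± 0.20, stellate cell markers (0 of 12 measured members passed (4 had an unadjusted p under 0.05); camera adjusted p = 0.0293; adjusted p = 0.371 with an estimated correlation) and the acute phase response (3 of 24 measured members rose and 21 did not pass; camera adjusted p = 0.0293; adjusted p = 0.520 with an estimated correlation), with the endotoxin coreceptor Cd14, not well above background in baseline B, at 2.89 ± 0.51. Effects were more negative for male-biased genes (8 of 20 measured members fell and 12 did not pass; camera adjusted p = 1.21e-09; adjusted p = 0.266 with an estimated correlation), cytochrome P450 (3 of 22 measured members fell and 19 did not pass; camera adjusted p = 0.000769; adjusted p = 0.0581 with an estimated correlation), with Cyp2c29 at -2.57 ± 0.30, and glucose metabolism (3 of 25 measured members fell and 22 did not pass; camera adjusted p = 0.0134; adjusted p = 0.277 with an estimated correlation), with Slc2a2 at -2.12 ± 0.25. Phase II conjugation (3 of 37 measured members rose, 2 fell and 32 did not pass; camera adjusted p = 0.0305; adjusted p = 0.319 with an estimated correlation), with Ugt3a1 at -2.31 ± 0.42, and bile acid genes (1 of 19 measured members fell and 18 did not pass; camera adjusted p = 0.0374; adjusted p = 0.319 with an estimated correlation), with Abcc3 at -2.35 ± 0.36, were lower too. Clock genes went both ways (2 of 14 measured members rose, 5 fell and 7 did not pass; camera adjusted p = 0.00921; adjusted p = 0.371 with an estimated correlation), with Arntl, not well above background in baseline B, at 2.64 ± 0.42 and Clock at 0.70 ± 0.16. Adjusted over the list alone, 14 macrophage, 16 cell cycle, 4 interferon, 4 female-biased, 5 endothelial and 5 acute phase genes were more positive, 5 and 7 phase II genes and 2 and 8 clock genes were more positive and more negative, and 10 male-biased, 9 P450, 6 glucose and 1 bile acid genes were more negative. The stellate cell markers list lost the call without baseline A replicate 1, chronic T3 replicate 1 or baseline B replicate 3 (adjusted p 0.0603 to 0.0747). The bile acids list lost the call without baseline A replicate 2, acute T3 replicate 3, chronic T3 replicate 1 or baseline B replicate 3 (adjusted p 0.0644 to 0.121). The acute phase response list lost the call without baseline A replicate 3, acute T3 replicate 3, chronic T3 replicate 1 or baseline B replicate 1 (adjusted p 0.0534 to 0.0924). The phase II conjugation list lost the call without baseline A replicate 3, chronic T3 replicate 2 or baseline B replicate 1 (adjusted p 0.0558 to 0.116). Clock lost the call without acute T3 replicate 3 (adjusted p = 0.0629). The interferon response list had a mean of 0.47 without chronic T3 replicate 1. The phase II conjugation list had a mean of -0.12 without baseline A replicate 3. Cdh5, Clock and the acute phase response list lost the call under median scaling (adjusted p 0.144 to 0.506).

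641 genes differed between the effects (limma), 343 more positive and 298 more negative after chronic T3. The count was 411 without baseline A replicate 1, 311 and 350 without acute T3 replicates 1 and 3, 366 without baseline B replicate 3, and 234 under median scaling, with 36.3% more positive in place of 53.5% and the median of all genes at -0.11. 110 genes were called in the same direction in the acute and the chronic comparison and 6 in opposite directions, where independent calls give 22.4 and 21.02. Across the 8976 genes, which are not independent replicates, the acute and chronic effects had a Pearson r of 0.207 (Spearman rho 0.160), and the chronic and withdrawal effects, which share baseline B, had r = 0.444 (rho 0.428), where data with no effects gave a mean r of 0.459.

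Whether repeated injections blunt the acute response was asked of the 190 acute genes, of which 39 had a called difference of effects against their acute direction. Thrsp, Dbp, Usp2, Cpsf4l and Wipf3 headed those that had risen, and Chka, Arntl, Cdkn1a, Nupr1 and Clpx, a mitochondrial protease subunit (-1.32 ± 0.18 after acute T3), those that had fallen. All 7 clock genes called after acute T3, Dbp, Usp2, Tef, Arntl, Clock, Nr1d2 (0.80 ± 0.18) and Cry2 (0.78 ± 0.18), are in this set. Arntl, Chka and Cdkn1a, 3 of the 14 genes of the set that had fallen, were not well above background in baseline B, so that no further fall could be seen there. Choosing genes for a large acute effect favours a smaller second effect, and data simulated with equal effects gave a mean of 1.82 such genes and a highest of 125 in 100 draws. The acute risers as a whole had a median of 0.950 after acute and 0.572 after chronic T3, and those that fell had -0.884 and -0.393. The count was 13 and 22 without baseline A replicates 1 and 2, 10, 15 and 12 without acute T3 replicates 1, 2 and 3, and 25 and 22 without baseline B replicates 1 and 3. It was 18 under median scaling, 62 with no background correction and 12 without the genes called between the 2 baselines in the acute direction, the last chosen after seeing the data. Cry2 and Nr1d2 lost the call without baseline A replicates 1 or 2, or acute T3 replicates 1, 2 or 3 (adjusted p 0.0816 to 0.198). Cry2 lost the call under median scaling (adjusted p = 0.0716).

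Baseline B against baseline A compares untreated livers of the 2 experiment subsets. Clock output genes were far higher in baseline B: Dbp by 4.16 ± 0.60, Usp2 by 3.999 ± 0.43, the repressor Ciart by 3.63 ± 0.46 and Rgs16 by 4.45 ± 0.61. Thrsp was higher by 3.09 ± 0.32 (8.49-fold), about as much as after acute T3, and Fasn by 1.40 ± 0.41. Arntl (at least 4.001-fold), Chka (at least 3.31-fold) and Cdkn1a (at least 3.04-fold) were lower and not well above background in baseline B, and Tff3 (-3.25 ± 0.89) and Elovl3, a fatty acid elongase with a daily rhythm (-2.86 ± 0.47), were lower too. Dio1 (0.57 ± 0.27), Gpd2 (-0.066 ± 0.28), Cyp7a1 (0.24 ± 0.33), Bcl3 (-0.14 ± 0.28), Hr (-0.61 ± 0.38), Me1 (0.47 ± 0.28), Klf9 (-0.16 ± 0.15), Fgf21 (-2.32 ± 0.68), G6pc (0.11 ± 0.42), Pck1 (0.30 ± 0.24) and Cyp8b1 (-0.38 ± 0.22) did not pass. Of the clock list, 8 of 14 measured members rose, 2 fell and 4 did not pass (camera adjusted p = 4.94e-05; adjusted p = 0.423 with an estimated correlation), and in glucose metabolism 6 of 25 measured members rose and 19 did not pass (camera adjusted p = 0.000307; adjusted p = 0.248 with an estimated correlation). Cholesterol synthesis (2 of 17 measured members rose and 15 did not pass; camera adjusted p = 0.000307; adjusted p = 0.536 with an estimated correlation) and fatty acid synthesis (6 of 21 measured members rose, 1 fell and 14 did not pass; camera adjusted p = 0.0177; adjusted p = 0.536 with an estimated correlation) were higher as well. With the replicate number as a block, Fasn was not called (adjusted p = 0.0562) and Fgf21 was (adjusted p = 0.0401). Fasn lost the call without any 1 array compared but baseline B replicate 3 (adjusted p 0.0713 to 0.155). Tff3 lost the call without any 1 array compared (adjusted p 0.0506 to 0.108). Dbp was 3.57 without baseline A replicate 1 and 5.18 without replicate 3. Usp2 was 4.63 without baseline A replicate 3. Tff3 was -2.29 without baseline B replicate 1. Fasn lost the call under no background correction, normexp and median scaling (adjusted p 0.0709 to 0.0804).

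782 genes were called between the baselines (limma), 245 higher and 537 lower in baseline B, and 29.9% of all genes had groups that did not overlap, where chance gives 10%. 52 genes were called in the same direction here and after acute T3 and 2 in opposite directions. Independent calls give 7.07 and 9.48, and 100 draws of data with no effects gave 0 called alike, but part of the excess may come from baseline A, which both tests share. Across genes the 2 effects had r = 0.436 (mean of data with no effects 0.446, 59 of 100 draws as large) and a covariance of 0.0783 (0.0291, 4 of 100). The count was 128, 1717 and 230 without baseline A replicates 1, 2 and 3, 362 and 275 without baseline B replicates 2 and 3, 1186 with every detected probe tested, 501 with no filter on dim probes and 185 with only the 6 arrays compared. The share higher in baseline B was 31.3%, against 5.15% under median scaling, which set the median of all genes at -0.35, and 44.04% under cyclic loess.

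**Figure D2:**
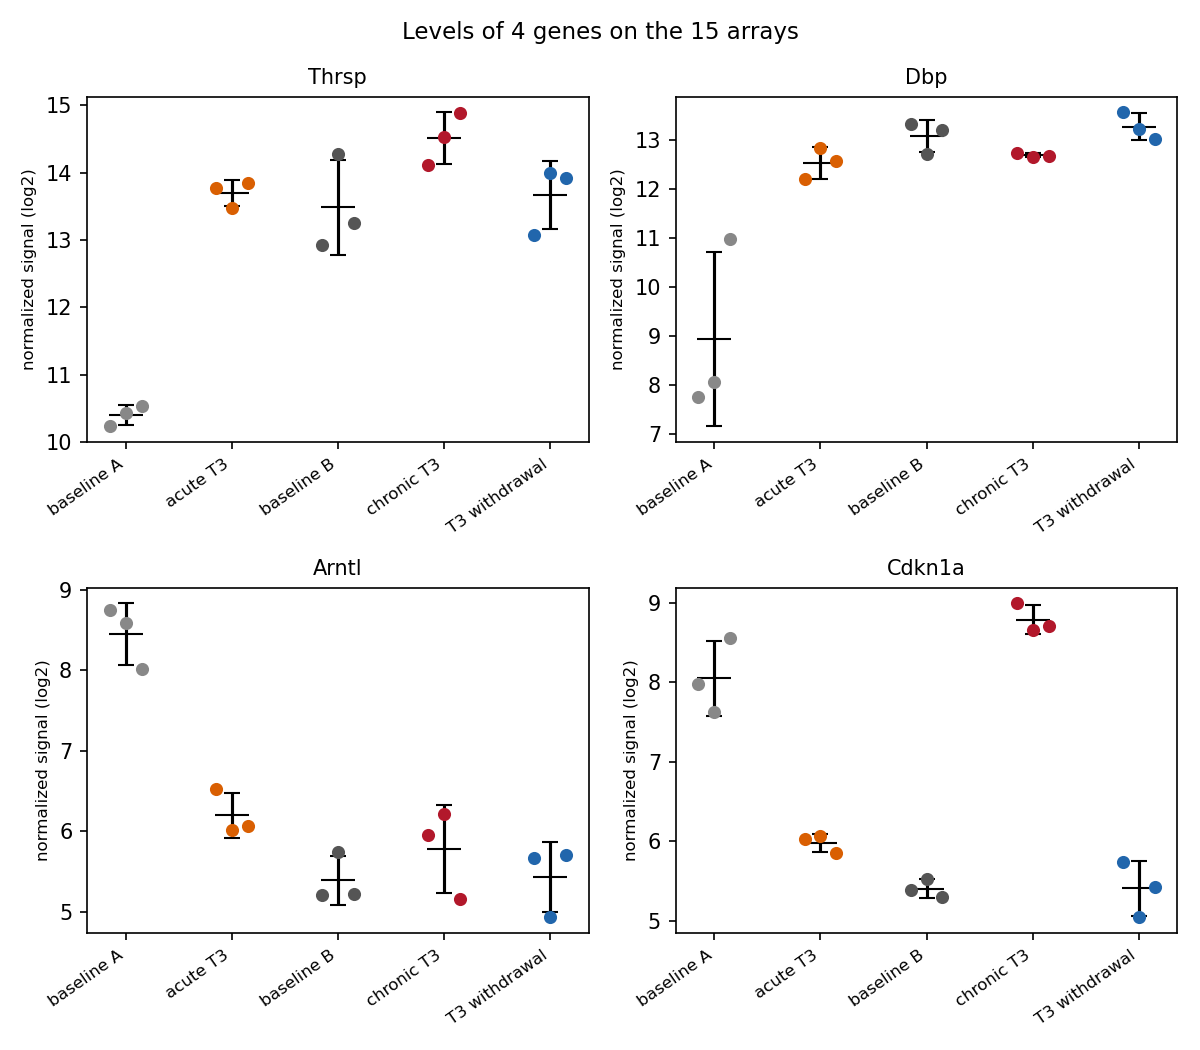
Normalized log2 signal (vertical axes) of Thrsp, Dbp, Arntl and Cdkn1a on each array (points) of the 5 groups (horizontal axes), with group means (bars) and SD (whiskers, n = 3). Mean Thrsp was 10.40 in baseline A, 13.70 after acute T3, 13.48 in baseline B and 14.51 after chronic T3.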

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

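The tests of explanations in this part were chosen after the results were seen, and the counts over other splits were planned before. Results stand here because the chronic effect differed from the acute effect, by a test of the difference itself. That held for 641 genes, for 13 lists and for 39 acute genes whose chronic effect was smaller, but for none of the lists with an estimated correlation (lowest adjusted p 0.0581). Among named genes, the chronic minus acute difference (log2) was above 0 for Cdkn1a (5.46), Tff3 (6.93), Fgf21 (4.60), Acnat2 (4.53), Cyp17a1 (4.08), Spink1 (3.92), Akr1c18 (5.82), Hr (2.36), Sult2a2 (4.93), Cxcl14 (4.72), Ntrk2 (4.46), Folr2 (2.10), Lyz2 (2.09), Mcm5 (3.18), Ifi27l2a (2.35), Cdh5 (0.99), Cd14 (2.89), Arntl (2.64) and Clock (0.70). It was below 0 for Cyp4a12b (-5.61), Cyp4a12a (-4.77), Ddah1 (-4.08), Nox4 (-3.67), Cyp2c23 (-3.27), Cyp2u1 (-3.23), Ildr2 (-3.18), Serpina7 (-3.09), Dbp (-4.003), Rgs16 (-3.63), Thrsp (-2.27), Cyp2c29 (-2.57), Slc2a2 (-2.12), Ugt3a1 (-2.31) and Abcc3 (-2.35). Those of Cdkn1a, Akr1c18, Hr, Sult2a2, Cxcl14, Ntrk2, Cyp2u1, Cd14 and Arntl rest in part on groups in which the gene was not well above background. Mean differences of the lists were bile acid genes (-0.36), glucose metabolism (-0.52), cytochrome P450 (-0.58), phase II conjugation (-0.25), male-biased genes (-1.59), female-biased genes (2.56), cell cycle (1.27), acute phase response (0.55), clock genes (-0.87), interferon response (0.87), macrophage markers (1.85), stellate cell markers (0.64) and endothelial markers (0.50). That of the interferon response was 0.47 without chronic T3 replicate 1, and that of phase II conjugation -0.12 without baseline A replicate 3.

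The 39 acute genes with a difference against the acute direction, clock genes among them, were weighed as a set against technical explanations. Background correction or scaling stays open for part of it, as there were 18 such genes under median scaling and 62 with no background correction. Another clock phase of the baseline A livers may account for part too: the phase score, clock genes that peak late in the light phase minus Arntl and Clock, was 1.98 ± 0.42 higher in baseline B than in baseline A with no overlap of arrays, and acute T3 arrays lay 1.25 ± 0.46 above baseline A and -0.74 ± 0.20 from baseline B. Another starting level is open, as 27 of the 39 genes were called between the untreated baselines in the acute direction, but 26 lay, after chronic T3, back from their level after acute T3 (median -0.30 in the acute direction), 11 of them at an adjusted p under 0.05. An adaptation to repeated T3 stays open as the biological explanation, because the baselines enter the choice of the set and the subset and the baseline go together in this design.

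Macrophage markers rose by a mean of 1.67 after chronic T3, though the list was not called with an estimated correlation (adjusted p = 0.246). A lower share of hepatocytes would raise the markers of all other cell types alike, and the macrophage rise exceeded that of endothelial markers by 1.37 ± 0.14 and that of stellate cell markers by 1.33 ± 0.20. Dimmer arrays or the scaling were argued against, as the rise over the median of all genes was at least 1.44 in 4 other settings. A candidate explanation is a rise of macrophages, or of their gene activity, in T3-treated liver, which is a hypothesis found and tested on the same data.

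After chronic T3, 11 of 20 male-biased genes fell and 5 of 9 female-biased genes rose and 1 fell, and neither list was called with an estimated correlation (adjusted p = 0.246 for each). RNA of female animals was argued against by Xist, detected on 0 chronic T3 arrays, with Eif2s3y detected on all 3. Probes that read near-identical copies do not account for the whole pattern, as the 9 male-biased genes outside such families had a mean change of -1.06 ± 0.36. Nor do dimmer arrays or the scaling, since the mean against the median of all genes was -1.28 or lower in 4 other settings. An effect of repeated T3 on the sex-dependent program of the liver may be what remains, as a hypothesis.

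Other splits of the same arrays were counted for each result. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Of these, 1 gave as many acute genes as the real 190, itself, and the highest other gave 0. For the other counts of genes the splits as large, the real value and the highest other were 1, 2052 and 5 for chronic T3, 2, 1 and 2 for withdrawal, 1, 1538 and 1 for withdrawal against chronic T3, and 1, 782 and 0 for the baselines. For lists they were 2, 10 and 12 in the acute, 2, 11 and 13 in the chronic and 1, 9 and 6 in the withdrawal comparison.

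For results on more groups 100 splits were drawn. As many genes with different effects as the real 641 came from 3 splits, the real one included (highest other 1027). That share does not exclude chance for a difference of effects, because 92 draws broke up the T3 groups (median 0 genes). Of the 7 others that kept the T3 groups whole and exchanged arrays between the baselines, 2 gave 960 and 1027 genes and 5 gave 172 to 253. Of the splits for the 1244 genes reversed on withdrawal, 1 gave as many, the real one (highest other 1243). The 3 others that kept the chronic T3 arrays together gave 1235 to 1243 and all the rest at most 2, so chance is excluded only for the chronic T3 arrays standing apart. As many smaller effects as the real 39 came from 4 splits (highest other 94), or 8 and 647 with T3 groups in either role. Chance is not excluded for these either, as 2 of the 7 that kept the T3 groups whole gave 55 and 94. Nor is it for the 13 lists with different effects (6; 15) or for the 1 gene not back at baseline (6; 3). The same holds for r = 0.207 of acute and chronic effects (95; 0.727) and r = 0.444 of chronic and withdrawal effects (58; 0.801).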

How the results depend on the processing

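All alternatives were planned except the gene-by-gene array weights and the leaving out of genes called between the baselines or of the 2 dimmest chronic T3 arrays, which were chosen after seeing the data. Of the values for named genes under the alternatives, 5786 kept their direction and side of the threshold, 322 lost their call, 90 gained one and 0 changed direction; for lists these were 1337, 134, 18 and 2, where the direction of a list is the one camera tests, against the other genes. Those that changed direction were Oxidative phosphorylation subunits in the chronic comparison (-0.13, median scaling in place of quantile) and Acute phase response in the withdrawal comparison (-0.0089, without T3 withdrawal replicate 2). The acute phase response list was at 0.41 without T3 withdrawal replicate 3, in place of 0.26, after withdrawal. The mean of the fatty acid oxidation list after withdrawal also changed sign without T3 withdrawal replicate 2 (0.017). Under median scaling the means of the 6 lists lower after withdrawal were above 0 (0.0022 to 0.28), where the median of all genes was 0.40.

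Counts that moved by more than 1.5 times follow, and the cause was not tested unless stated. With no background correction, and equally with the authors' values, there were 295 acute genes and 62 with a smaller effect. Under median scaling there were 123 acute, 888 chronic, 234 different, 18 smaller and 596 reversed. With no filter there were 109 acute, 501 between the baselines and 20 smaller, and 5 lists after withdrawal, with more genes tested. With every probe tested there were 1186 between the baselines. With only the arrays compared, which leaves fewer degrees of freedom, there were 93 acute, 898 chronic, 0 withdrawal, 802 withdrawal against chronic, 185 baseline, 18 smaller, 0 not back and 562 reversed, and with only the experiment subset 93 acute, 0 withdrawal and 0 not back (for the 0 counts, 662 and 353 genes passed at an unadjusted p in the full fit). The default array weights, whose estimate did not converge, gave 65 acute, 3 withdrawal, 79 baseline, 11 smaller and 3 not back. Gene-by-gene weights gave 1743 acute, 1146 different, 2512 baseline and 337 smaller. The methods rate baseline A replicate 1 in opposite ways (weights 0.000489 and 5.06), so that neither set of counts is preferred. Trend and robust moderation gave 288 acute. Unadjusted p gave 1322 acute, 3157 chronic, 662 withdrawal, 2719 withdrawal against chronic, 2082 different, 2675 baseline, 400 smaller, 353 not back and 2099 reversed. With an estimated correlation camera called 0 acute, 1 chronic, 0 withdrawal and 0 different lists, and fry called 0 withdrawal lists. The genes not back were 5 adjusted over the chronic genes alone, with fewer genes tested, 4 with both baselines as control and 2 without the 2 dimmest chronic T3 arrays, and 12 genes were smaller without those called between the baselines.

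Leaving out 1 array at a time, with the spread pooled over all groups, gave 48 to 164 acute, 1376 to 1995 chronic, 1 to 4 withdrawal, 1030 to 1460 withdrawal against chronic, 311 to 916 different and 128 to 1717 baseline genes, 10 to 47 smaller, 1 to 4 not back and 905 to 1228 reversed. Lists called were 6 to 11, 10 to 13, 5 to 11 and 11 to 14 in the acute, chronic, withdrawal and difference comparisons, and r was 0.124 to 0.275 for acute and chronic and 0.405 to 0.504 for chronic and withdrawal effects. With the replicate number as a block there were 154 acute, 1896 chronic, 1440 withdrawal against chronic, 569 different and 659 baseline genes. Beside Fasn and Fgf21 it changed no named gene or list between the baselines. Elsewhere the calls of Anxa3 after chronic T3 and of Nr1d2 and the cell cycle list after acute T3 ended (adjusted p 0.0506 to 0.0551), and Cyp8b1 between withdrawal and chronic T3 and T3-repressed genes after chronic T3 gained one (adjusted p 0.0395 to 0.0450). Signal over background limits what is tested: some genes, such as Thrb, were not detected on enough arrays.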

Other observations

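The tests of a T3 effect on the clock were chosen after the result was seen. Lists not called after chronic T3 still held called genes. In amino acid catabolism and the urea cycle 5 of 35 measured members rose, 6 fell and 24 did not pass (5 rose and 7 fell adjusted over the list alone; camera adjusted p = 0.285): the ornithine aminotransferase Oat fell (-2.41 ± 0.22), the urea cycle enzyme Otc fell (-0.96 ± 0.15), and Psat1 of serine synthesis, not well above background in baseline B, was at least 4.61-fold higher. In the unfolded protein and integrated stress response 6 of 21 measured members rose, 1 fell and 14 did not pass (6 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.835), with the asparagine synthetase Asns (1.92 ± 0.53) and the transcription factor Ddit3 (0.93 ± 0.19) up. In oxidative phosphorylation 5 of 67 measured members rose, 3 fell and 59 did not pass (1 fell adjusted over the list alone; camera adjusted p = 0.835), such as Ndufb2 (-0.70 ± 0.13). Among apolipoproteins 3 of 20 measured members rose, 4 fell and 13 did not pass (4 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.857; mean 0.041, median -0.024, tested direction down), with Apoa4 (2.66 ± 0.53) up and Angptl8, which restrains lipoprotein lipase, down (-2.41 ± 0.42). In autophagy and lysosome 2 of 41 measured members rose, 4 fell and 35 did not pass (1 rose and 4 fell adjusted over the list alone; camera adjusted p = 0.558), with the autophagy kinase Ulk1 up (0.80 ± 0.15), as it was after acute T3 (1.21 ± 0.15). In the acute phase response 5 of 24 measured members rose, 1 fell and 18 did not pass (5 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.237), with ceruloplasmin, Cp (0.64 ± 0.14), up. The fibrinogen chain Fgb, called as a fall (-0.90 ± 0.24), was not well above background in either group, so its value is not read as a change. Asns lost the chronic call without chronic T3 replicate 1 or baseline B replicate 1 (adjusted p 0.0614 to 0.0786). Fgb lost the chronic call without baseline B replicate 3 (adjusted p = 0.0688). Apoa4 was 1.86 without chronic T3 replicate 1 and 3.32 without replicate 3. Cp and Fgb lost the chronic call under median scaling (adjusted p 0.0733 to 0.256).

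Other small lists were not called after chronic T3 either. Of T3-repressed genes 2 of 5 measured members fell and 3 did not pass (2 fell adjusted over the list alone; camera adjusted p = 0.0649), Serpina7 among them. Of genes of thyroid hormone receptors and transport 1 of 12 measured members rose, 1 fell and 10 did not pass (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.943; mean -0.21, median 0.091), Dio1 and Serpina7. In lymphocyte and NK cell markers 2 of 4 measured members rose and 2 did not pass (2 rose adjusted over the list alone; camera adjusted p = 0.168), among them Cd52 (1.63 ± 0.35). In red blood cell markers 2 of 6 measured members fell and 4 did not pass (2 fell adjusted over the list alone; camera adjusted p = 0.907; mean -0.24, median 0.47), among them the heme synthesis enzyme Alas2 (-1.74 ± 0.31). In cholangiocyte markers 1 of 4 measured members rose, 1 fell and 2 did not pass (1 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.857; mean -0.18, median 0.31), with Anxa3 (0.68 ± 0.21) up. In pancreas acinar markers 2 of 4 measured members rose, 1 fell and 1 did not pass (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.201), with the elastase Cela2a (2.81 ± 0.24) and Spink1 (2.58 ± 0.77) up and the amylase Amy2a5 down (-0.40 ± 0.098). In mitochondrial biogenesis 2 of 16 measured members rose, 2 fell and 12 did not pass (2 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.835), with Gpd2 up and the deacetylase Sirt3 down (-0.70 ± 0.14), and in the immediate early and heat shock list 3 of 13 measured members fell and 10 did not pass (3 fell adjusted over the list alone; camera adjusted p = 0.338), with Fos (-2.21 ± 0.37) down. Of clock genes 2 of 14 measured members fell and 12 did not pass (1 fell adjusted over the list alone; camera adjusted p = 0.415), the nuclear receptor Rora (-0.74 ± 0.16) and the repressor Nr1d1 (at least 1.91-fold lower). Anxa3 and Spink1 lost the call without any 1 array compared but chronic T3 replicate 3 (adjusted p 0.0526 to 0.124). Nr1d1 lost the call without chronic T3 replicates 1 or 2, or baseline B replicates 1 or 3 (adjusted p 0.0670 to 0.130). Spink1 was 3.32 without chronic T3 replicate 3 and 1.81 without replicate 1. Nr1d1 lost the call under no background correction, normexp, median scaling and cyclic loess (adjusted p 0.0596 to 0.107). Amy2a5, Anxa3, Rora and Spink1 lost the call under median scaling (adjusted p 0.0503 to 0.153).

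A hypothesis was that T3 raises the phase score and still does after 14 injections. The score would then have been higher after chronic T3 than in baseline B. It was not (-0.24 ± 0.11), and a shift the other way stays open. After withdrawal the difference was 0.23 ± 0.086. The covariance across genes of the chronic and withdrawal effects was 0.0807, against a mean of 0.0315 in data with no effects, where 6 of 100 draws were as large.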
